A study of Homo sapiens with 6 samples.

How the data were processed

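Total RNA of HCT116 cells taken 4 h after 1 dose of 2 Gy or after 5 doses of 2 Gy was set against RNA of non-irradiated cells on 6 dual-colour arrays, 3 per schedule. Per the labels, control RNA carried Cy3 and irradiated RNA Cy5 on every array. Per the file headers, the deposited scanner files give linear spot intensity as quantified by ImaGene version 9.0, at 532 and 635 nm, with neither background correction nor normalization. The deposited series table holds log2 ratios of irradiated over control, centred on 0 in each array; how the authors normalized them is not stated in the sources used here. Each of its columns correlated with the ratios computed from the same array (r from 0.974 to 0.999). Whether arrays share control RNA, and the time between doses, are likewise not stated.

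Each array has 45220 spots, 43376 of them for genes, and 153 negative control spots. Values were computed with R 4.3.3 and limma 3.58.1. The mean spot intensity of each channel was corrected with normexp (offset 50) on the foreground alone, because the files hold no background columns, and log2 ratios were normalized within arrays by loess (span 0.3, control spots at weight 0). Spots with quality value 3 in the files (2.85% to 4.05% of gene spots per array) were left out, and those with value 2 were kept. The files do not give the meaning of these values. Spots with value 3 were bright (median Cy3 intensity 8530, against 210 for other gene spots), so abundant transcripts were lost more often. Spots of a probe were averaged. A probe was kept if it exceeded the 95th percentile of the negative control spots in at least 1 channel on at least 3 of 6 arrays. This held for 26598 of 41000 probes.

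Probes were named by transcript accession (23680), current symbol (2802) or synonym (1123) in a RefSeq gene table, or else by the name in the files (2209), and 11186 had no gene name. The probe with the highest mean intensity stood for a gene. Genes needed at least 2 values per schedule: of 14845 genes above background 14313 were tested, and 532 were lost to removed spots. Median intensity was 117 to 278 in Cy3 and 66.8 to 300.0 in Cy5, against 38.5 to 187 and 22.4 to 176 for negative controls. Arrays have no read depth, and their number limits the precision. Where a channel was above background on none of a schedule's arrays, a bound is given in place of the fitted fold.

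One limma fit over all 6 arrays, with a mean per schedule (4 residual degrees of freedom; prior degrees of freedom 8.99), gave moderated two-sided tests of each schedule against control and of their difference. P values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The 25 gene lists named with the results were tested on the 12664 genes measured on all 6 arrays by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the lists of a comparison. Counts and medians of a list cover all its measured members, whereas these tests cover only those on all 6 arrays. The tests took in 46 of 59 p53 targets, 35 of 38 G1/S, 22 of 27 cholesterol, 27 of 32 histone and 26 of 26 interferon genes. They took in 20 of 28 immediate early, 11 of 20 ATF4, 9 of 18 ribosomal and 9 of 22 oxidative phosphorylation genes. Fold changes are per gene, errors are SD between arrays of a schedule, or SE for a difference. The image pair in the file headers gave the slide of each array.

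Named genes were chosen by rule: in each comparison the 8 largest rises and the 8 largest falls past the threshold with one sign on every array (for the difference, no overlap between schedules), up to 4 members of each list with the smallest p, and always CDKN1A, MDM2, GDF15, FAS, BAX, BBC3, CCNB1, CDK1, PLK1 and CCNE2. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where a choice is said to be later. The background columns that the plan named do not exist in the files, and the exact rule for a spot above background was set once the file layout was known.

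Alternatives were no background correction, offset 0, median centring, quantile scaling of intensity between arrays, no filter and a stricter filter on dim probes, removed spots kept, the mean of all probes, each probe on its own, the replicate number or the slide as a block, array weights, an intensity trend with a robust prior, the series table, each schedule fitted alone, separate channels, a minimum fold of 1.5 and leaving out each array. The spot median and the slide as a random block were added after seeing the data.

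The steps were tested on simulated data with 200 changed genes among 12664. Changes of 1.5-, 2- and 3-fold were called in 67.2%, 100% and 100% of cases after the single dose, 56.7%, 98.5% and 100% after fractionation, and 17.9%, 80.6% and 100% in the difference. Of the calls, 9.64%, 2.30% and 4.35% were unchanged genes. A list shifted by 0.3 was called in each comparison and 0 of 24 unmoved lists were (camera). In these simulations genes varied independently of each other and slides had no effect. In the data, estimated correlations within a list reached 0.46 for G2/M and 0.51 for hypoxia genes. The simulated lists therefore cannot show how often such lists are called without a shift. In simulated spots, normexp and loess returned a planted log2 ratio of 1 as 0.97 and as -1.01 for decreases.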

Results

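The series measured transcripts of HCT116, a human cell line of colorectal cancer, 4 h after ionizing radiation. Cells received 1 dose of 2 Gy or 5 doses of 2 Gy (5 x 2 Gy), and non-irradiated cells of the line were the control. The time between the 5 doses is not given in the sources used here. Each of 6 dual-colour arrays held control RNA in Cy3 and irradiated RNA in Cy5, with 3 biological replicates per schedule. No array has the dyes exchanged, so a preference of a probe for one dye stays in every ratio against control and cancels in the difference between schedules only where it is common to all arrays. Median spot intensity was 117 to 278 in Cy3 and 66.8 to 300.0 in Cy5, and the number of arrays limits the precision. In all, 14313 genes were tested, of which 12664 had a value on all 6 arrays. The arrays lay on 3 slides: single-dose replicates 1 and 3 with fractionated replicate 3 on slide 1, single-dose replicate 2 with fractionated replicate 1 on slide 2, and fractionated replicate 2 alone on slide 3.

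After a single dose of 2 Gy, 18 of 59 measured p53 targets, among them genes of cell cycle arrest and cell death, were higher than control at 4 h. The list was called up with a preset correlation between genes, and not with an estimated one (adjusted p = 0.511 with an estimated correlation). FAS, a death receptor, rose 2.81-fold (log2 ratio 1.49 ± 0.18, SD, n = 3, adjusted p = 5.56e-05), and CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, rose 2.35-fold (1.23 ± 0.08, adjusted p = 0.000891). BTG2, an antiproliferative gene, rose 3.16-fold (1.66 ± 0.50), and GADD45A, a DNA damage response gene, rose 2.63-fold (1.39 ± 0.39). Of 38 genes of G1/S and DNA replication 7 fell: MCM5, a subunit of the replicative helicase, by 0.73 ± 0.33 (1.66-fold lower, adjusted p = 0.0209). This comparison asks which transcripts differ from non-irradiated cells after 1 dose.

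In limma, 858 genes passed a Benjamini-Hochberg adjusted p of 0.05 after the single dose, 282 higher and 576 lower than control, of which 191 and 398 differed by at least 1.5-fold. Of the 59 measured p53 targets, 18 rose, 0 fell and 41 did not pass. Adjusted over the list alone, 25 rose and 3 fell. As a set it was called up (median log2 ratio 0.21, adjusted p = 2.46e-08), and this call was lost with adjusted p = 0.511 with an estimated correlation. AEN, an apoptosis-enhancing nuclease, rose 2.47-fold (1.30 ± 0.42), and MDM2, the ubiquitin ligase that limits p53, rose 1.74-fold (0.80 ± 0.24, adjusted p = 0.0185). PLK2, a polo-like kinase, rose 2.26-fold (1.17 ± 0.19), and IER5, an immediate early response gene, rose 2.83-fold (1.5 ± 0.09), although another probe of IER5 read 0.03 and without single-dose replicate 2 the gene read -0.08. BAX (0.33 ± 0.67) and BBC3 (-0.51 ± 0.16, n = 2), which promote apoptosis, did not pass, and other probes of BBC3 read 1.12 (adjusted p = 0.0176) and 0.38 (adjusted p = 0.210). With the removed spots kept, BBC3 passed at -0.64 (adjusted p = 0.0131). Other probes of BAX read 0.33 and -0.25. GDF15, a secreted p53 target, lost too many spots to be tested, and with the removed spots kept it read 1.11 (adjusted p = 0.0195). MDM2 missed the threshold without single-dose replicate 1 (0.66), 2 (0.88) or 3 (0.86), AEN without replicate 1 (1.32) or 3 (1.09), and PLK2 without replicate 1 (1.13) or 3 (1.10).

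After the single dose, of 38 genes of G1/S and DNA replication, 0 rose, 7 fell and 31 did not pass, and 9 fell adjusted over the list alone. In camera it was called down (median -0.23, adjusted p = 0.00461, and adjusted p = 0.511 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell by 0.71 ± 0.25 on its brightest probe, while another probe read 0.08. Of 39 genes of G2/M and mitosis, 1 fell (PIF1, a DNA helicase, -0.56 ± 0.18, other probes -0.19 and -0.40), 0 rose, 38 did not pass, and none passed adjusted over the list alone. In camera it was called down (median -0.24, adjusted p = 0.0128, and adjusted p = 0.686 with an estimated correlation). CCNB1 (-0.54 ± 0.42, n = 2), CDK1 (0.14 ± 0.26) and PLK1 (-0.24 ± 0.24), which drive entry into mitosis, and CCNE2 (-0.17 ± 0.30), a cyclin of G1/S, did not pass. However, another probe of PLK1 read -0.71 (adjusted p = 0.0485, limma on each probe). Without single-dose replicate 2 neither list was called, with medians of -0.22 for G1/S and -0.17 for G2/M. UHRF1 missed the threshold without single-dose replicate 1 (-0.63) or 2 (-0.65), MCM5 without replicate 1 (-0.65) or 3 (-0.61), and PIF1 without replicate 1 (-0.46), 2 (-0.64) or 3 (-0.59). Of the 48 genes that the naming rule gave and that passed in this comparison, 33 lost the call without at least 1 array.

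Among 28 genes of the immediate early and growth factor response, 4 rose after the single dose, 0 fell and 24 did not pass, and 7 rose adjusted over the list alone. The set was called up (median 0.23, adjusted p = 0.0166, and adjusted p = 0.686 with an estimated correlation). ATF3, a stress transcription factor, rose 3.06-fold (1.61 ± 0.58, another probe read 0.69), DUSP1, a phosphatase of MAP kinases, rose 1.66-fold (0.73 ± 0.07), and JUND, an AP-1 subunit, rose 1.62-fold (0.69 ± 0.07). ATF3 read 0.69 and did not pass without fractionated replicate 1 or 2, when its brightest probe was no longer measured, and JUND lost its call without single-dose replicate 1 (0.71), 2 (0.71) or 3 (0.65). DUSP1 lost its call without single-dose replicate 1 (0.72). Of 27 genes of cholesterol and lipid synthesis, 2 rose, 0 fell and 25 did not pass, and 7 rose adjusted over the list alone. The set was called up (median 0.27, adjusted p = 0.00895, and adjusted p = 0.686 with an estimated correlation). MSMO1, a sterol synthesis enzyme, read 0.55 ± 0.32 (adjusted p = 0.0412, another probe 0.26) and STARD4, a sterol carrier, read 0.84 ± 0.54 (adjusted p = 0.0466), and neither passed without single-dose replicate 1 (0.63 and 1.09), 2 (0.67 and 0.88) or 3 (0.37 and 0.55). Of 20 genes of the ATF4 and unfolded protein response, 1 rose, 0 fell and 19 did not pass, and 2 rose adjusted over the list alone. Camera called it up (median 0.22, adjusted p = 0.0101, and adjusted p = 0.535 with an estimated correlation). HERPUD1, of protein quality control in the endoplasmic reticulum, rose 1.63-fold (0.70 ± 0.07) and missed the threshold without single-dose replicate 1 (0.67) or 3 (0.74). The immediate early list was not called without single-dose replicate 3 (median 0.02), and the ATF4 list not without replicate 2 (median 0.23).

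The largest decreases that the naming rule gave after the single dose included genes known from other tissues. LCE3C, of the cornified envelope of skin, was 7.43-fold lower (-2.89 ± 0.33, adjusted p = 1.26e-05, irradiated channel above background on 1 of 3 arrays), GP6, a collagen receptor of platelets, was 6.23-fold lower (-2.64 ± 0.31), and ARID1B, a subunit of a chromatin remodelling complex, was 4.96-fold lower (-2.31 ± 0.32). MS4A6A, ZFPM1, a cofactor of GATA factors, SLC22A7, an organic anion transporter, CROCC, of the ciliary rootlet, and KISS1R, the kisspeptin receptor, were lower by 4.81-, 4.00-, 3.61-, 3.47- and 3.34-fold. The irradiated channel of MS4A6A was above background on 1 of 3 arrays, and other probes of ARID1B and CROCC read -0.05 and -0.03. No array has the dyes exchanged. For these genes and the differentiation markers below, a preference of the probe for Cy3 cannot be told apart from a decrease. Among 16 intestinal differentiation markers, 3 fell, with CHGA of endocrine cells at -0.96 ± 0.07, while 0 rose and 13 did not pass. Adjusted over the list alone 4 fell. As a set it was called down (median -0.21, adjusted p = 0.0166, and adjusted p = 0.686 with an estimated correlation). Without single-dose replicate 3 (median -0.17) or fractionated replicate 3 (-0.24), or with the slide as a block (-0.07), this list was not called. Without single-dose replicate 1, 2 or 3, 126, 316 or 124 genes passed in all, against 1375 or 1387 without fractionated replicate 2 or 3. The count was 176 with median centring in place of loess, 315 with the slide as a block and 3337 with array weights.

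After 5 doses of 2 Gy, 36 of 59 p53 targets, 13 of 26 interferon-stimulated genes and 13 of 32 histone genes were higher than control. These lists were called up, the histone list not with an estimated correlation (adjusted p = 0.418 with an estimated correlation). CDKN1A rose 4.96-fold (log2 ratio 2.31 ± 0.49, SD, n = 3, adjusted p = 1.26e-05), FAS rose 4.86-fold (2.28 ± 0.04, adjusted p = 1.5e-06), TP53I3, an oxidoreductase induced by p53, rose 4.33-fold (2.11 ± 0.52) and SERPINB5, the tumour suppressor maspin, rose 3.96-fold (1.98 ± 0.32). IFIT1, an antiviral gene, rose 4.02-fold (2.01 ± 0.53, adjusted p = 6.35e-05). CCNE2, a cyclin of G1/S, fell by 1.29 ± 0.26 (2.44-fold lower, adjusted p = 0.000235) and MCM5 fell by 1.13 ± 0.37 (2.19-fold lower). This comparison asks which transcripts differ from non-irradiated cells after the whole course.

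In limma, 1772 genes passed after fractionation, 831 higher and 941 lower, of which 450 and 513 differed by at least 1.5-fold. Of 59 p53 targets, 36 rose, 2 fell and 21 did not pass (39 and 2 adjusted over the list alone). In camera it was called up (median 0.64, adjusted p = 1.09e-21) also with an estimated correlation (adjusted p = 0.0397). HES2, a repressor of the HES family, rose 3.16-fold (1.66 ± 0.22), BTG2 rose 3.46-fold (1.79 ± 0.84) and MDM2 rose 2.09-fold (1.06 ± 0.51, adjusted p = 0.00232). GADD45A, IER5, AEN and PLK2 read 0.87, 1.08, 0.90 and 0.52, against 1.39, 1.5, 1.30 and 1.17 after the single dose. None of them passed when the schedules were compared directly (limma). BBC3, which promotes apoptosis, was lower (-0.66 ± 0.14, n = 2, adjusted p = 0.0234) on its brightest probe, also with the removed spots kept (-0.80, adjusted p = 0.00217), but other probes read 1.34 (adjusted p = 0.00126) and 0.36 (adjusted p = 0.201). BAX read -0.08 ± 0.04 (n = 2) and did not pass, while other probes read 0.96 (adjusted p = 0.000482) and 0.21 (adjusted p = 0.464). The probe that stood for a gene changed with the arrays used: BBC3 read 0.36 without single-dose replicate 1 or 3, 0.12 without fractionated replicate 2 and 1.68 without fractionated replicate 3, and BAX read 0.92 and 1.00 without fractionated replicate 2 and 3. GDF15 read 1.94 with the removed spots kept (adjusted p = 0.000519). PIK3C2A, a lipid kinase, passed at 1.76 ± 2.22 with fractionated replicate 2 at 4.32. It read 0.48 (adjusted p = 0.0427) without that array and missed the threshold without single-dose replicate 2 or 3 (1.76).

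Of 26 interferon-stimulated genes, 13 rose after fractionation, 1 fell and 12 did not pass (18 and 2 adjusted over the list alone). The set was called up (median 0.48, adjusted p = 6.56e-09, and adjusted p = 0.0397 with an estimated correlation). OASL, of the oligoadenylate synthetase family, rose 3.24-fold (1.70 ± 0.29), IFIT2 rose 2.51-fold (1.33 ± 0.26, control channel above background on 1 of 3 arrays) and IRF9, which binds interferon response elements with STAT proteins, rose 2.00-fold (1.00 ± 0.16), although another probe of IRF9 read -0.01. The gene that fell was IFI6, an interferon-induced mitochondrial protein, at -0.68, chosen here after its values were seen. With the removed spots kept it read 1.44 (adjusted p = 6.58e-05). After the single dose the list was not called (median 0.06, adjusted p = 0.496): HERC5, a ligase of ISG15, rose by 0.47 ± 0.08, IFI6 read -0.91 ± 0.14 (0.30, adjusted p = 0.156, with the removed spots kept and 0.33 in the series table), and 24 did not pass, with 1 higher and 1 lower adjusted over the list alone. HERC5 missed the threshold without single-dose replicate 1 (0.44), 2 (0.47) or 3 (0.51), and IFI6 without replicate 1 (-0.97) or 3 (-0.84).

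After fractionation, of 32 replication-dependent histone genes, 13 rose, 5 fell and 14 did not pass (15 and 7 adjusted over the list alone). Camera called it up (median 0.22, adjusted p = 0.0110, and adjusted p = 0.418 with an estimated correlation). The members with the smallest p were H2B genes, which encode a core histone: H2BC21 rose 2.31-fold (1.21 ± 0.17), H2BC5 rose 2.15-fold (1.11 ± 0.35), H2BC4 rose 2.03-fold (1.02 ± 0.16) and H2BC14 rose 1.82-fold (0.86 ± 0.02). Other probes of H2BC21 read 0.24 and 0.72, and another of H2BC5 read 0.53. Without fractionated replicate 2 the histone list was not called (median 0.25). After the single dose 2 histone genes rose, 2 fell and 28 did not pass (2 and 3 adjusted over the list alone, median -0.06, adjusted p = 0.339). Of the 38 genes of G1/S and DNA replication, 24 fell, 0 rose and 14 did not pass (29 fell adjusted over the list alone). As a set it was called down (median -0.48, adjusted p = 8.60e-12, and adjusted p = 0.0397 with an estimated correlation). UHRF1 fell by 0.96 ± 0.29 (another probe -0.36) and ORC1, of the origin recognition complex, fell by 0.87 ± 0.19. Of 39 genes of G2/M and mitosis, 3 fell, 0 rose and 36 did not pass, and none passed adjusted over the list alone. As a set it was called down (median -0.17, adjusted p = 0.0353, and adjusted p = 0.653 with an estimated correlation). KIF11, the spindle motor Eg5, fell by 0.45 ± 0.10, HJURP, a chaperone of centromeric histone, fell by 0.61 ± 0.33 and PRC1, of the central spindle, fell by 0.57 ± 0.42. CCNB1 (-0.41 ± 0.48), CDK1 (0.22 ± 0.31) and PLK1 (-0.04 ± 0.60) did not pass, and another probe of PLK1 read -0.57 (adjusted p = 0.0691). The G2/M list was not called without fractionated replicate 2 (median -0.10) or 3 (-0.08) and stood at -0.39 without replicate 1. KIF11, HJURP and PRC1 each lost the call without fractionated replicate 3 (-0.41, -0.44 and -0.40) or single-dose replicate 3. KIF11 lost it also without single-dose replicate 1 or fractionated replicate 1 (-0.50) or 2 (-0.42), HJURP without fractionated replicate 1 (-0.62) and PRC1 without fractionated replicate 2 (-0.49).

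Among 27 genes of cholesterol and lipid synthesis, 7 fell after fractionation, 0 rose and 20 did not pass (9 fell adjusted over the list alone). In camera it was called down (median -0.33, and -0.21 without fractionated replicate 3, adjusted p = 4.01e-05, and adjusted p = 0.418 with an estimated correlation). SCD, which makes monounsaturated fatty acids, fell by 0.92 ± 0.15 (1.89-fold lower), ACACA, the carboxylase that starts fatty acid synthesis, fell by 0.66 ± 0.27 and SREBF2, the transcription factor of sterol genes, fell by 0.62 ± 0.35 but did not pass without fractionated replicate 3 (-0.43). Of 28 immediate early and growth factor genes, 2 rose, 4 fell and 22 did not pass (2 and 5 adjusted over the list alone, median -0.23, adjusted p = 0.0531). CCN1, a matricellular protein, fell by 0.87 ± 0.32, FOSL1, an AP-1 subunit, fell by 0.80 ± 0.01, and ATF3 (1.76 ± 0.11, n = 2) and AREG, an EGF receptor ligand (0.89 ± 0.01, n = 2), rose. ATF3 read 0.13 and 0.20 without fractionated replicate 1 and 2, and another of its probes read 0.56. The immediate early median was -0.93 on fractionated replicate 3, against 0.12 and 0.06 on replicates 1 and 2, and the list was called with the slide as a block (-0.24, adjusted p = 0.0323) and in each fit without 1 of the other 5 arrays, with medians from -0.34 to -0.27. The fractionated arrays lie on different slides, so the slide block takes up the spread between them and its p does not measure it. Of 20 ATF4 and unfolded protein genes, 3 rose, 2 fell and 15 did not pass (4 and 2 adjusted over the list alone, median -0.005, mean 0.004, camera direction up, adjusted p = 0.292), and without fractionated replicate 3 the list was called up (median 0.16). Of 16 intestinal differentiation markers, CHGA fell by 0.93 ± 0.37, MUC2 of goblet cells fell by 0.76 ± 0.18 (another probe -0.23), 1 more fell, 0 rose and 13 did not pass (4 fell adjusted over the list alone). In camera it was called down (median -0.12, adjusted p = 0.0432, and adjusted p = 0.629 with an estimated correlation) but not without fractionated replicate 1 (-0.13), 2 (-0.21) or 3 (-0.17).

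The largest decreases after fractionation were GP6 (6.0-fold lower, -2.58 ± 0.85), ARID1B (4.99-fold lower, -2.32 ± 0.95, another probe read 0.03) and LCE3C (4.55-fold lower, -2.19 ± 0.55). ZFPM1, KISS1R, ZNF775, a zinc finger gene, and SLC22A7 were lower by 4.22-, 3.55-, 3.49- and 3.31-fold, and another probe of ZNF775 read 0.01. MS4A6A was dim in the irradiated channel and was at least 2.88-fold lower. GP6, ARID1B, LCE3C, ZFPM1, KISS1R and SLC22A7 were among the largest decreases after the single dose too. A preference of these probes for Cy3 cannot be told apart from a decrease. The count of genes fell from 1772 to 727 without fractionated replicate 1 and to 919 without replicate 3. It was 596 with median centring and 3597 with the slide as a block. That block takes up the spread between fractionated arrays, each on a different slide. With array weights 1352 genes passed, against 3337 after the single dose, and with each schedule fitted alone 724 against 2778. Which schedule gave the higher count thus depended on how the spread was estimated.

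**Figure D1:**
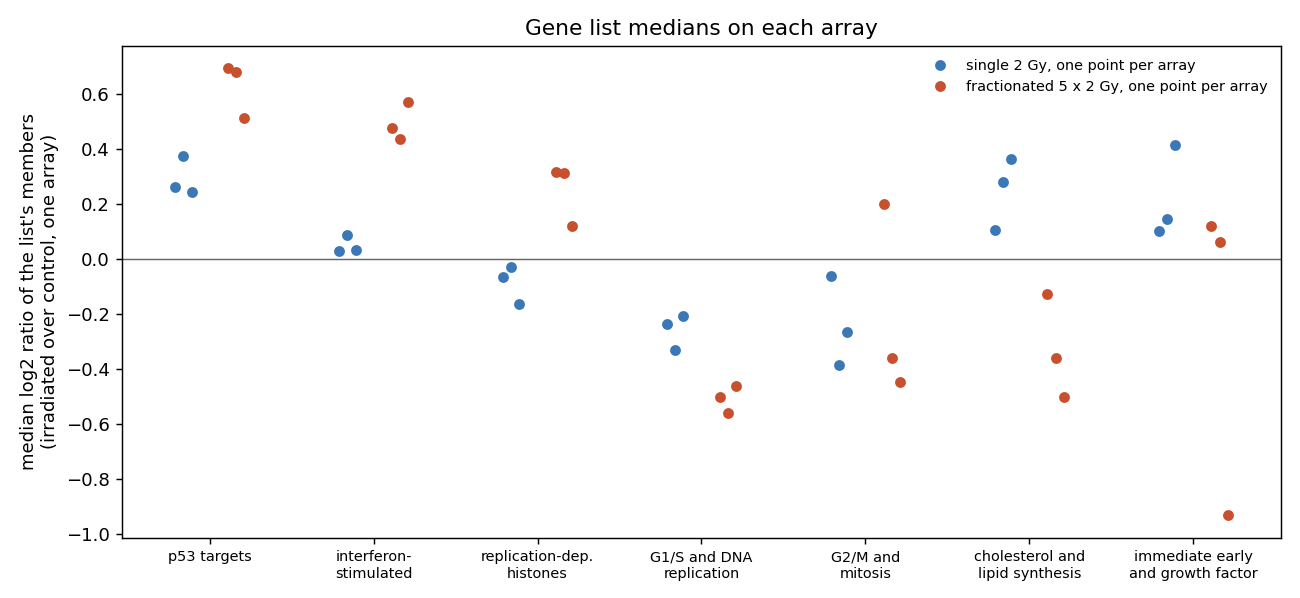
Median log2 ratio (irradiated over control, y axis) of the measured members of 7 gene lists (x axis) on each array, with 1 point per array and replicates in order from left to right within a group. The p53 list lies between 0.24 and 0.37 on the single-dose arrays and between 0.51 and 0.69 on the fractionated arrays, and the immediate early list lies at -0.93 on fractionated replicate 3.

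The responses to both schedules overlapped. In all, 107 genes were higher than control under both, against 16.4 for independent lists, and 378 were lower under both, against 37.9. Among the 12664 genes on all 6 arrays these counts were 87 and 341, and in 20 simulations of as many genes, with no effect and control RNA shared by arrays of the same number, the means were 0 and 0.05 (limma). Without any effect hardly a gene passes the adjusted threshold, so means near 0 were fixed in advance. They cannot show how much shared control RNA adds to the overlap of lists as long as the measured ones. At an unadjusted p under 0.05 the simulated means were 68.8 and 66.0, against 516 and 1016 measured among these genes. A slide effect, 1 control pool for all arrays and a preference of probes for one dye, each of which would add to the overlap, were not simulated. With the slide as a block the overlap fell from 485 to 260 genes, and to 222 with the slide as a random block, an alternative chosen after seeing the data. The genes higher in both include CDKN1A, FAS, BTG2, MDM2 and ATF3, with a median log2 ratio of 0.65 after the single dose and 0.69 after fractionation over all 107. The 378 genes lower in both, among them GP6, LCE3C, ZFPM1 and MCM5, had medians of -0.71 and -0.74. Where other probes measured the same gene, they carried a median share of 0.142 of the called probe's ratio over 115 of these lower genes and of 0.363 over 36 of the higher ones (permutation test of the difference, one-sided, p = 0.00275). CCN1, ESRP2, KLK6, RPL28 and SLC30A1 passed in opposite directions, against 52.0 genes for independent lists. CCN1 read 0.78 ± 0.42 (n = 2) after the single dose, but other probes read -0.01 and 0.37 and it missed the threshold without single-dose replicate 1 (0.02), 2 (0.78) or 3 (-0.14). ESRP2, a splicing regulator of epithelial cells, was chosen after its values were seen (-0.47 and 0.45). Across the 14313 genes, which are not independent replicates, the mean ratios of both schedules correlated with Pearson's r of 0.613 and Spearman's rho of 0.573. Genes called under neither schedule gave r of 0.466. Without any effect, r was -0.003 in simulated data where each array has its own control and 0.50 where both schedules share their control RNA, and the sources used here do not say which holds. The covariance was 0.062 measured and 0.0107 in the simulation with shared controls. Arrays on the same slide but of different schedules had a mean r of 0.59 over 3 pairs, against 0.47 over 5 pairs of the same schedule on different slides and 0.31 over 6 pairs that share neither.

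**Figure D2:**
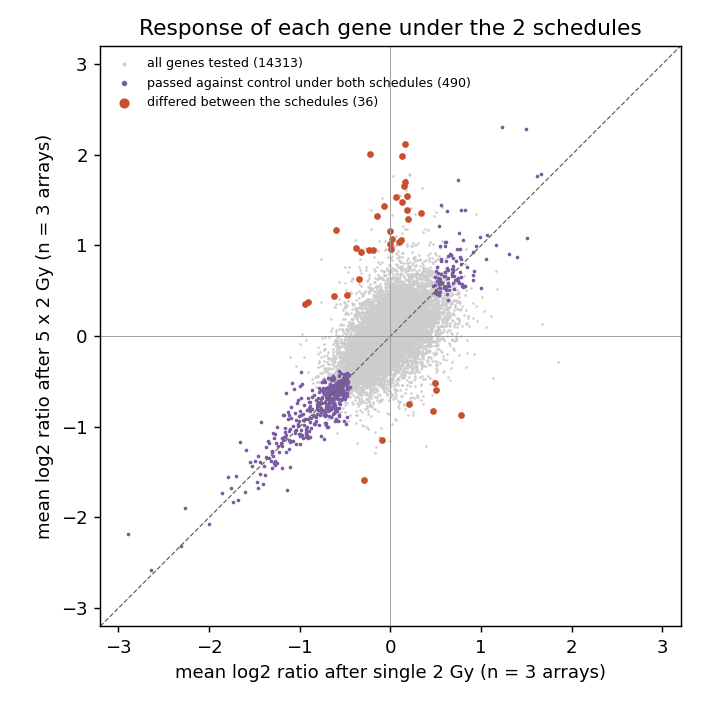
Mean log2 ratio after the single dose (x axis) and after 5 x 2 Gy (y axis), 1 point per gene, with the line of equality dashed. Genes that passed under both schedules were lower than control under both in 378 cases and higher under both in 107, and 29 of the 36 genes that differed between the schedules lie above it.

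Compared directly, 36 genes differed between the schedules, among them 4 of 59 p53 targets and 2 of 26 interferon-stimulated genes, all 6 higher after fractionation. Both lists were called up, the p53 list not with an estimated correlation (adjusted p = 0.111 with an estimated correlation). IFIT1 was 4.70-fold higher after 5 x 2 Gy than after 2 Gy (log2 difference 2.23 ± 0.26, SE, n = 3 against 3, adjusted p = 0.00508), TP53I3 was 3.86-fold higher (1.95 ± 0.24), SERPINB5 was 3.63-fold higher (1.86 ± 0.20) and HES2 was 2.84-fold higher (1.51 ± 0.19). KLK6, a secreted protease, was 3.40-fold higher (1.77 ± 0.23), OASL 2.89-fold (1.53 ± 0.23) and KRTAP3-1, a keratin-associated protein, 2.79-fold (1.48 ± 0.18). CCN1 was 3.13-fold lower (-1.65 ± 0.25), and GADD45B, a stress-induced gene, and IFITM1, an interferon-induced membrane protein, were each 2.45-fold lower (-1.29 ± 0.21 and -1.29 ± 0.19). This comparison asks whether the response depends on the schedule. Total dose and schedule change together, so it cannot part them.

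In limma, 36 genes passed in this comparison, 29 higher and 7 lower after fractionation, and 1333 had an unadjusted p under 0.05. FDXR, a mitochondrial reductase induced by p53, was 2.83-fold higher (1.5 ± 0.24, n = 2 against 2), and SLC30A1, a zinc exporter, TOE1, an RNA exonuclease, RPL28, a ribosomal protein, and MAT2A, which makes S-adenosylmethionine, were 2.15-, 2.07-, 2.01- and 1.93-fold lower. Among list members that passed, LAMA3, a laminin chain, read 1.47 (other probes 0.51 and 0.31), ACTA2, smooth muscle actin, 1.2, AKR1B10, an aldo-keto reductase, 1.06 and H2BC4 1.02. CDKN1A (1.08 ± 0.23, adjusted p = 0.0853), FAS (0.79 ± 0.17, adjusted p = 0.0966) and CCNE2 (-1.11 ± 0.21, adjusted p = 0.0503) did not pass, nor did MDM2 (0.26), BAX (-0.42), BBC3 (-0.15), CCNB1 (0.13), CDK1 (0.08), PLK1 (0.20), or GDF15 with the removed spots kept (0.83, adjusted p = 0.453). Within slide 1 the differences of IFIT1, TP53I3 and SERPINB5 were 2.43, 2.19 and 1.87, and within slide 2 they were 1.30, 1.16 and 1.61. Within the slides IFITM1 read -1.61 and -0.95, and GADD45B read -1.50 and -1.60. The naming rule allows no overlap between the schedules in this comparison. The sign within each slide was therefore fixed by the choice of genes, and only the sizes are informative.

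**Figure D3:**
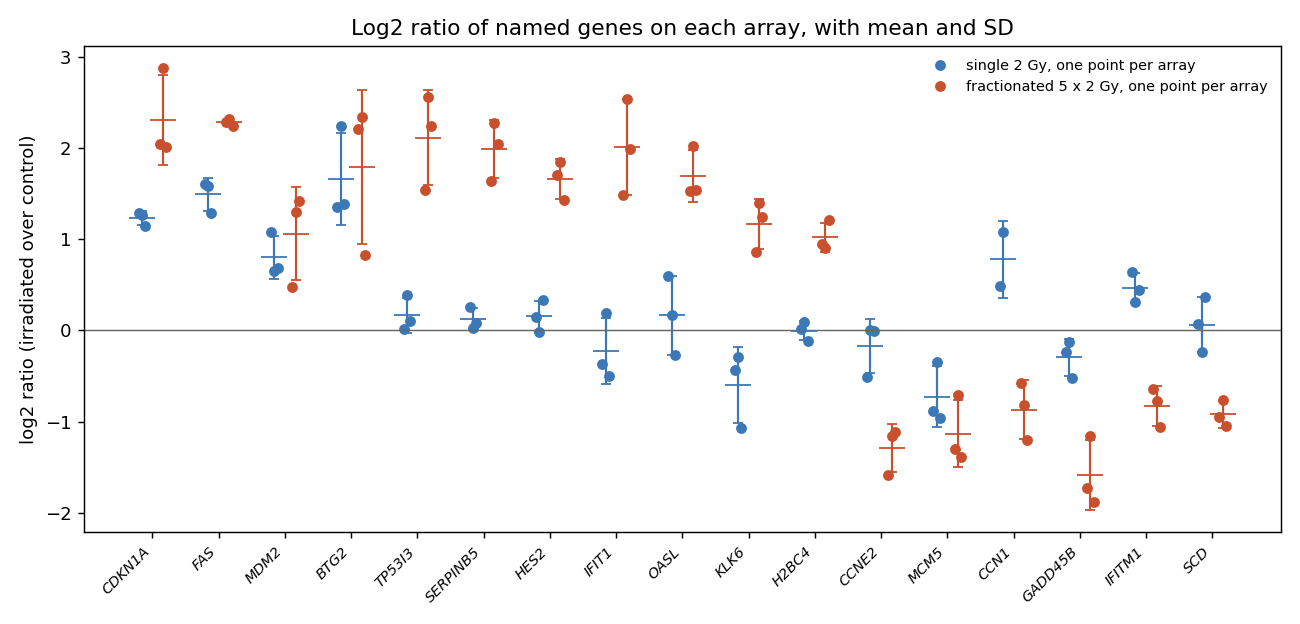
Log2 ratio (irradiated over control, y axis) of 17 named genes (x axis) on each array, 1 point per array, with bars for the mean and SD of each schedule. IFIT1 lies between -0.50 and 0.19 after the single dose and between 1.49 and 2.54 after fractionation, while GADD45B and IFITM1 are lower after fractionation.

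Of the 59 p53 targets, 4 were higher after fractionation, 0 lower and 55 did not pass (16 and 1 adjusted over the list alone). The set was called up (median difference 0.35, adjusted p = 2.42e-11, and adjusted p = 0.111 with an estimated correlation), with 0.26 within slide 1 and 0.35 within slide 2. Of 26 interferon-stimulated genes, 2 were higher, 0 lower and 24 did not pass (12 higher adjusted over the list alone). The set was called up (median 0.32, adjusted p = 2.42e-11) also with an estimated correlation (adjusted p = 0.0362), and within the slides it read 0.35 and 0.37. RIGI, a sensor of viral RNA (1.07, adjusted p = 0.122), and IRF9 (0.81) did not pass over all genes, and IFI6 read 1.15 with the removed spots kept (adjusted p = 0.0308). Of 32 histone genes, 1 was higher and 31 did not pass (11 higher adjusted over the list alone, median 0.33, adjusted p = 2.78e-07, and adjusted p = 0.111 with an estimated correlation, 0.31 and 0.28 within the slides). Of 38 genes of G1/S and DNA replication, none passed over all genes (limma, 4 lower adjusted over the list alone). Camera called it down (median -0.25, adjusted p = 1.02e-07, and adjusted p = 0.111 with an estimated correlation, -0.22 and -0.25 within the slides). Of 27 genes of cholesterol and lipid synthesis, none passed over all genes (limma), 14 were lower adjusted over the list alone. As a set it was called down (median -0.62, adjusted p = 6.06e-15, and adjusted p = 0.111 with an estimated correlation, -0.81 and -0.34 within the slides). ACACA (-1.02, adjusted p = 0.0626, another probe -0.25), SCD (-0.98, adjusted p = 0.0712) and HMGCS1, of sterol synthesis (-0.88, adjusted p = 0.0853), were its members with the smallest p. Other probes of SCD read -0.77 and -1.34, and another of HMGCS1 read -1.24 (adjusted p = 0.0425, limma on each probe). Of 28 immediate early and growth factor genes, CCN1 was lower and 27 did not pass (6 lower adjusted over the list alone). Camera called it down (median -0.40, adjusted p = 1.02e-07, and adjusted p = 0.238 with an estimated correlation), but it read -1.12 within slide 1 and -0.01 within slide 2, and -0.07 without fractionated replicate 3. The interferon median was 0.49 without single-dose replicate 2 and 0.51 without fractionated replicate 3. The G2/M list was not called (median 0.06, mean 0.02, adjusted p = 0.986, 0 of 39 passing, also adjusted over the list alone), but was called down (-0.15) without fractionated replicate 1. Its median was -0.26 within slide 1 and 0.55 within slide 2, in opposite directions. The ATF4 list was not called either (median -0.04, adjusted p = 0.185, 0 of 20, also adjusted over the list alone), but was called down (-0.08) without single-dose replicate 3 and with the slide as a block (-0.18, adjusted p = 0.0213). The intestinal differentiation list was not called (median -0.004, mean 0.03, camera direction down, adjusted p = 0.986, 0 of 16, also adjusted over the list alone).

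The count of genes that differed between the schedules rested on few arrays: it was 0 (limma, 785 genes at an unadjusted p under 0.05) without single-dose replicate 3, where IFIT1, TP53I3, SERPINB5, KLK6, HES2 and KRTAP3-1 each stood at an adjusted p of 0.0674. It was 7, 10, 22 and 67 without single-dose replicate 1, single-dose replicate 2, fractionated replicate 2 and fractionated replicate 3. These 6 genes passed without each of the other 5 arrays, and the other 13 passing genes of the naming rule did not. With median centring in place of loess 4 genes passed, and 82 with the slide as a block.

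The other 16 lists were not called by camera in any comparison of the fit without a block, the smallest adjusted p being 0.252 for endothelial markers after the single dose, 0.0531 for hypoxia genes after fractionation and 0.0671 for ribosomal and heat shock genes in the difference. With the slide as a block, hypoxia genes were called up after fractionation (adjusted p = 0.0323) and in the difference (median 0.32, adjusted p = 0.000953). Since the fractionated arrays lie on different slides, the call after fractionation does not measure the spread between them. With this block extracellular matrix genes were called up after the single dose (adjusted p = 0.0401) and down in the difference (adjusted p = 0.0243). Of 43 DNA repair genes, 2 fell after the single dose (2 adjusted over the list alone) and 1 rose and 6 fell after fractionation (1 and 6 adjusted over the list alone), with medians of -0.09 and -0.13: FANCI, of the Fanconi anaemia pathway, fell by 0.78 ± 0.34 after fractionation, with other probes at -0.03 and -0.35. Of 26 apoptosis genes outside the p53 list, 0 changed after the single dose and 3 rose and 1 fell after fractionation, with the same counts adjusted over the list alone (medians 0.02, with a mean of -0.006, and 0.10): CASP2, a caspase, fell by 0.83 ± 0.21 (other probes -0.26 and -0.49) and BCL2A1, an inhibitor of apoptosis, rose by 0.66 ± 0.13. Of 18 NF-kB and inflammatory genes, 0 passed after the single dose (1 higher and 1 lower adjusted over the list alone) and 3 rose after fractionation (3 adjusted over the list alone, medians -0.03, with a mean of 0.02, and 0.07): BIRC3 rose by 0.86 ± 0.17 (control channel above background on 1 of 3 arrays) and SOD2 by 0.73 ± 0.40 (n = 2). Of 13 MHC class I and antigen processing genes, 0 and 3 rose (0 and 3 adjusted over the list alone, medians 0.09 and 0.01), with TAP1, the peptide transporter, at 0.65 ± 0.34 after fractionation, though not past the threshold without fractionated replicate 1 (0.45). Of 20 hypoxia genes, 0 and 3 rose (0, and 6 with 1 lower, adjusted over the list alone, medians -0.04, with a mean of 0.02, and 0.32), among them BNIP3L, of mitophagy, at 0.70 ± 0.42 after fractionation (another probe 0.26), which did not pass without fractionated replicate 1 (0.55) or 3 (0.59). The hypoxia median was 0.69 on fractionated replicate 1, -0.03 on replicate 2 and 0.09 on replicate 3, and 0.08 without replicate 1. Of 12 heat shock genes, 1 fell after the single dose (1 adjusted over the list alone) and 2 rose after fractionation (2 adjusted over the list alone, medians -0.07, with a mean of 0.003, and 0.19). Of 20 NRF2 and antioxidant genes, 1 rose after the single dose (0 adjusted over the list alone) and 6 after fractionation (6 adjusted over the list alone), with medians of 0.02 (mean -0.02) and -0.02 (mean 0.16, camera direction up). AKR1B10 rose 2.11-fold (1.07 ± 0.28, control channel above background on 2 of 3 arrays) and FTH1, ferritin heavy chain, 2.00-fold (1.00 ± 0.27, n = 2) after fractionation.

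Of 24 integrin and focal adhesion genes none passed under either schedule (limma), over all genes or adjusted over the list alone (medians -0.17 and -0.06). Of 24 extracellular matrix genes, none passed after the single dose (limma) and after fractionation 1 rose and 1 fell, with the same counts adjusted over the list alone. LAMA3 rose 2.51-fold (1.33 ± 0.46, other probes 0.33 and 0.35). The medians were 0.03 and -0.04. Of 14 WNT target and intestinal stem cell genes, 1 fell under each schedule (2 higher and 2 lower, then 1 higher and 2 lower, adjusted over the list alone, medians -0.002, with a mean of 0.007, and 0.02, with camera direction down). Of 13 mesenchymal transition markers, none passed after the single dose (limma) and after fractionation ACTA2 rose 2.62-fold (1.39 ± 0.20), while TAGLN, an actin-binding protein of smooth muscle, fell by 1.22 ± 0.33 (2.33-fold lower) and FOXC2 fell by 0.61 ± 0.20, the last not without fractionated replicate 1 (-0.53). The counts adjusted over the list alone were the same (0, then 1 and 2), and the medians were -0.12 and -0.02. Of 18 ribosomal protein genes that kept enough spots, out of 50, 4 rose after the single dose (5 adjusted over the list alone) and 1 rose and 2 fell after fractionation (1 and 2 adjusted over the list alone). The medians were 0.33 and 0.05, camera's direction after fractionation was down, and with the removed spots kept the list was called up under both schedules (0.40 and 0.36). Of 22 oxidative phosphorylation genes, none passed under either schedule (limma), over all genes or adjusted over the list alone (medians -0.001, with a mean of 0.06, and 0.003, with a mean of -0.01). Markers of other cell types gave 1 lower gene each under both schedules among 4 fibroblast markers (THY1 at -1.11 ± 0.35 and -1.16 ± 0.34) and 3 endothelial markers (CLDN5 at -1.66 ± 0.11 and -1.17 ± 0.36), with the same counts adjusted over the list alone. For THY1 and CLDN5 too, a preference of the probe for Cy3 cannot be told apart from a decrease. The fibroblast medians were -0.18 and 0.03 (mean -0.23) and the endothelial -0.14 and -0.15. Of 10 leukocyte markers, 0 passed after the single dose (1 lower adjusted over the list alone) and 2 were lower after fractionation (2 adjusted over the list alone, medians -0.09 and -0.08). Between the schedules, of these 16 lists, LAMA3, ACTA2 and AKR1B10 were the members that passed over all genes. Adjusted over the list alone 1 repair gene was lower, 2 hypoxia and 3 NRF2 genes higher, 1 integrin gene higher, 1 matrix gene higher and 3 lower, 1 mesenchymal marker higher and 1 lower and 1 ribosomal gene lower. Fry, which asks whether a list moves one way on balance, called 4, 8 and 2 lists after the single dose, after fractionation and in the difference, p53 targets among them each time.

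Probes without a gene name gave 75 higher and 189 lower of 4931 after the single dose, 142 and 319 after fractionation, and 1 and 0 in the difference.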

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

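Tests chosen only after their result was seen were the equal size of decreases under both schedules, the medians with median centring, the slide test split between the immediate early list and the other lists, and the correlation of the array that lies alone on its slide. A direct test of the difference between schedules brought up 36 genes and, in camera with a preset correlation, 6 lists. The named genes among them, as the log2 response after 5 x 2 Gy minus that after 2 Gy, were IFIT1 (2.23), TP53I3 (1.95), SERPINB5 (1.86), KLK6 (1.77), OASL (1.53), HES2 (1.51), FDXR (1.5), KRTAP3-1 (1.48), LAMA3 (1.47), ACTA2 (1.2), AKR1B10 (1.06), H2BC4 (1.02), MAT2A (-0.95), RPL28 (-1.01), TOE1 (-1.05), SLC30A1 (-1.11), GADD45B (-1.29), IFITM1 (-1.29) and CCN1 (-1.65). The lists, by median difference, were p53 targets (0.35), histones (0.33), interferon-stimulated genes (0.32), G1/S and DNA replication (-0.25), immediate early genes (-0.40) and cholesterol and lipid synthesis (-0.62). With an estimated correlation the interferon list kept its call (adjusted p = 0.0362 with an estimated correlation) and the other 5 lost theirs (adjusted p = 0.238 for immediate early genes and 0.111 for each other list). The estimate for the interferon list was itself negative (-0.022). Probes without a gene name, which enter no comparison of genes, differed from control in 264 cases after the single dose and 461 after fractionation.

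Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 36 genes and the highest other gave 0 (limma), 1 of 10 with as many, and 1333 genes had an unadjusted p under 0.05 in the real split. With the sign of 1 array turned, the highest count was 0 (limma) against 858 after the single dose (3533 unadjusted), and 0 against 1772 after fractionation (4183 unadjusted), 1 of 4 sign patterns with as many in each case. These splits are too few for a share under 0.05.

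For 378 genes the ratio was lower than control under both schedules, to a like extent. The test here asked whether the loess step itself made these decreases. With median centring in its place 83.3% of these genes stayed below -0.5 under both schedules. This fell short of a bound of 90 set beforehand, so the planned test could not decide. With loess itself 86.5% stayed below -0.5. The medians were -0.68 and -0.76 with median centring, against -0.71 and -0.74 with loess. These medians, compared after the result was seen, argue against loess as the whole source. Median centring leaves a trend with intensity in the ratios, so the values do not test such a trend. Most single calls nonetheless ended with median centring, where the count fell from 858 to 176. A preference of single probes for Cy3 is a candidate explanation that stays open: other probes of these genes showed a median share of 0.142 of the called ratio, against 0.363 for genes higher under both (permutation p = 0.00275), and the median difference between schedules was -0.10 over 1139 genes lower under either, against 0.32 over 1006 genes higher under either. A decrease after irradiation that is equal under both schedules stays open too, as no array has the dyes exchanged.

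For 6 lists camera called a difference between the schedules with a preset correlation, and for 1, the interferon list, also with an estimated one (adjusted p = 0.0362, against 0.111 to 0.238 for the others). The tables argue against the control channel as the source, since 0 lists drew over 50% of the difference from Cy3 (shares from -9.0% to 13.1%). The slide test set beforehand covered all 6 lists and could not decide. Split off after the result was seen, the 5 lists other than the immediate early list kept at least a share of 0.544 of the difference within slide 1 and within slide 2. For them this speaks against the slide as the whole source, though each of these slides held only 1 fractionated array. Over all 6 lists the lowest share was 0.0374, that of the immediate early list, whose difference was -0.0149 within slide 2 and -1.12 within slide 1. For this list the schedule and the state of fractionated replicate 3 cannot be told apart, as that array alone carries the difference within slide 1 and without it the median is -0.07. For the other 5 lists a response that depends on schedule or total dose may hold and was not tested apart from a difference in how the cultures of each schedule were handled.

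Fractionated replicate 2 stood apart from the other fractionated arrays: its mean r with them, across genes, was 0.366 against 0.556 between them, a difference of -0.19, and genes are not independent replicates. The tables argue against an array that belongs to the single dose, since its median over p53 targets was 0.68 and the highest single-dose array read 0.37. Its slide and its sample cannot be told apart, because it lies alone on its slide. No biological explanation was tested for this array.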

How the results depend on the processing

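The spot median and the slide as a random block were chosen after seeing the data, all other alternatives before. The list values below are median log2 ratios. Using the scanner's own processed signals was not run, since the files hold none. Where a result changed, the cause was not tested, except that leaving out arrays or genes leaves fewer to test. Signal over background limits the arrays: 51.7% to 71.9% of gene probes in Cy3 and 56.2% to 66.3% in Cy5 exceeded the 95th percentile of the negative controls.

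With the preset correlation every alternative kept direction and call for p53 targets (0.17 to 0.36 after the single dose, 0.55 to 0.75 after fractionation, 0.24 to 0.49 in the difference) and interferon-stimulated genes (0.37 to 0.65 after fractionation, 0.26 to 0.55 in the difference). The same held for G1/S genes after fractionation (-0.51 to -0.47) and in the difference (-0.34 to -0.19), and for histones in the difference (0.28 to 0.44). Cholesterol genes kept theirs after fractionation (-0.42 to -0.21) and in the difference (-0.76 to -0.50), and immediate early genes in the difference (-0.58 to -0.07). The correlation of both responses ranged from 0.466 to 0.691 over 25 alternatives.

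Camera with an estimated correlation leaves medians as they are but ended calls after the single dose for p53 targets (0.21), G2/M (-0.24), G1/S (-0.23), immediate early (0.23), ATF4 (0.22), cholesterol (0.27) and differentiation (-0.21). After fractionation it ended those of G2/M (-0.17), histones (0.22), cholesterol (-0.33) and differentiation (-0.12). In the difference it ended those of p53 targets (0.35), G1/S (-0.25), histones (0.33), immediate early (-0.40) and cholesterol (-0.62). The size of the correlation is not all that differs between the preset and the estimated test. For interferon genes after fractionation the estimate was -0.022, below the preset 0.01, yet the unadjusted camera p rose from 7.87e-10 to 0.00234. A call lost with the estimate therefore does not show that correlation between genes removed it. Fry ended the calls that camera lost with the estimate, except those of p53 targets, of G1/S after the single dose and of histones after fractionation. It added fibroblast (-0.18) and endothelial markers (-0.14) after the single dose. After fractionation it added DNA repair (-0.13), apoptosis (0.10), NRF2 (-0.0194) and fibroblast markers (0.0347). For the last 2 the median hides the direction: the NRF2 mean was 0.16 with camera direction up, and the fibroblast mean -0.23 with camera direction down.

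Counts of genes are given for the single dose, fractionation and the difference, against 858, 1772 and 36 with 485 common to both schedules. Median centring gave 176, 596 and 4 (142 common), and the share of higher genes after the single dose fell from 32.9% to 19.3%. It ended the G2/M calls (-0.18 after the single dose, -0.18 after fractionation) and called ribosomal genes in the difference (-0.25). No background correction gave 19 in the difference and called immediate early genes after fractionation (-0.28). Offset 0 gave 23 and ended the G2/M call after fractionation (-0.19). The spot median gave 21 in the difference and called hypoxia genes after fractionation (0.31). A minimum fold of 1.5 left 963 after fractionation and 313 common.

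Without a filter on dim probes 19 genes passed in the difference, and differentiation markers were not called (-0.0840 after the single dose, -0.0597 after fractionation). Calls were added for immediate early (-0.23) and hypoxia genes (0.32) after fractionation, and for hypoxia (0.16), heat shock (0.25) and ribosomal genes (-0.16) in the difference. The stricter filter ended the immediate early call after the single dose (0.10). It left 1 endothelial marker, CLDN5, which passed after both schedules (-1.66 and -1.17), and called DNA repair (-0.14) and hypoxia genes (0.33) after fractionation.

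With removed spots kept, ribosomal genes were called up after the single dose (0.40) and, turning camera's direction, after fractionation (0.36). Differentiation (-0.21 and -0.11) and, after the single dose, ATF4 (0.15) were not called. Hypoxia (0.24, and 0.16 in the difference) and NRF2 genes (0.24 and 0.15) were. IFI6 after the single dose (0.30) and RPL12 (0.75) and RPS2 (0.43) after fractionation turned upward. The series table did the same for ribosomal genes (0.31, and 0.29 after fractionation), differentiation (-0.23 and -0.15), ATF4 (0.17), hypoxia (0.24 and 0.15), NRF2 (0.23 and 0.14), IFI6 (0.33), RPL12 (0.64) and RPS2 (0.31). It kept 74.2%, 88.4% and 55.6% of calls. The mean of all probes ended the differentiation call after fractionation (-0.12) and added oxidative phosphorylation after the single dose (0.13), and extracellular matrix (-0.0432) and ribosomal genes (-0.15) in the difference. BAX (0.45) and BBC3 (0.54) turned upward after fractionation.

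Array weights gave 3337 after the single dose, 1352 after fractionation, 67 in the difference and 774 common. They ended the calls of G2/M (-0.20) and cholesterol (0.22) after the single dose and G2/M (-0.12) after fractionation, and called hypoxia genes (0.38, and 0.19 in the difference). Each schedule fitted alone gave 2778 and 724, no call for differentiation after the single dose (-0.21), and calls for immediate early (-0.23) and hypoxia genes (0.32) after fractionation. With array weights and with each schedule alone, more genes passed after the single dose than after fractionation, unlike in the main fit. Separate channels gave 1907, 238 in the difference and 928 common. They ended the calls of G2/M (-0.21) and immediate early (0.30) after the single dose and of G2/M (-0.18) and differentiation (-0.19) after fractionation, and called ribosomal genes in the difference (-0.0660).

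The slide as a block gave 315, 3597 and 82 with 260 common. It ended the differentiation call after the single dose (-0.0747) and called extracellular matrix genes (0.0630). It also called immediate early (-0.24) and hypoxia genes (0.32) after fractionation, and ATF4 (-0.18), hypoxia (0.32) and extracellular matrix genes (-0.15) in the difference. Each fractionated array lies on a different slide, so the block takes up the spread between them. Its count and calls against control after fractionation therefore do not measure that spread. As a random block the slide gave 275 after the single dose, 161 in the difference and 222 common. It ended the G2/M call after fractionation (-0.17) and called endothelial markers after the single dose (-0.11) and hypoxia (0.22) and ribosomal genes (-0.14) in the difference.

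Whether replicate numbers pair the samples is not settled. Deviations from the group means correlated at -0.12, 0.28 and 0.28 for numbers 1, 2 and 3. Across schedules, arrays of numbers 2 and 3 correlated best with their own number, and those of number 3 also share a slide. Both arrays of number 1 correlated best with an array of the other schedule on their own slide (0.18 and 0.14). The main fit treats the samples as unpaired. The replicate block gave 1728 genes after the single dose, 2589 after fractionation, 127 in the difference and 861 common. It called immediate early (-0.18) and hypoxia genes (0.32) after fractionation and changed no other call of a list.

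Leaving out 1 array at a time leaves 2 in a group, and genes then measured on a lone array are assumed to vary like the others. Counts ranged from 124 to 1387, 727 to 2558 and 0 to 67 (limma), with 112 to 843 common. Lists whose call changed in at least 1 such fit after the single dose were ATF4 (0.19 to 0.27), G1/S (-0.25 to -0.21), G2/M (-0.30 to -0.17), immediate early (0.0209 to 0.28) and differentiation (-0.24 to -0.17). After fractionation they were ATF4 (-0.0394 to 0.16), DNA repair (-0.15 to -0.0563), G2/M (-0.39 to -0.0835), hypoxia (0.0818 to 0.40), immediate early (-0.34 to 0.0842), differentiation (-0.21 to -0.12) and histones (0.21 to 0.28). In the difference they were ATF4 (-0.24 to 0.0153), G2/M (-0.15 to 0.14, called down without fractionated replicate 1), ribosomal (-0.36 to -0.0897), extracellular matrix (-0.17 to -0.0172), heat shock (0.12 to 0.41) and hypoxia (0.13 to 0.42). Genes that turned were IER5 (-0.0763 to 1.55), CCN1 (-0.14 to 0.78) and BBC3 (-0.51 to 1.12) after the single dose, and BAX (-0.0846 to 1.00) and BBC3 (-0.66 to 1.68) after fractionation.

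Of 124 values of counts and the correlation, 79 stayed and 45 moved. Of values of lists, 586 of 625 after the single dose, 566 of 625 after fractionation and 564 of 600 in the difference kept direction and side of the threshold. Calls were lost in 31, 23 and 9 and gained in 8, 34 and 26. For named genes 2215 of 2630, 2339 of 2602 and 2274 of 2469 did, with 200, 194 and 112 losses and 210, 57 and 83 gains.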
